A study of Homo sapiens with 10 samples.

How the data were processed

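Expression was measured with total RNA of H157 cells on 20 arrays, 2 for each of 10 samples, carrying the long oligonucleotides of a human genome set. Per the labels, cells were kept overnight in low serum before treatment, RNA was reverse transcribed with aminoallyl nucleotides and coupled to Cy3 or Cy5, and each sample's arrays carried the treated RNA once in each dye. Each array's deposited scanner table gave the mean intensity of each spot in the red and green channels, in arbitrary units, with extreme pixels trimmed and local background already subtracted, and its local background intensity. It also held a deposited quality score per spot between 0 and 1 and a deposited calibrated ratio of red over green, which was the ratio of the intensities times a constant per array. The scanner and image software are not given in the sources used here. The series matrix held the authors' log2 ratio per probe for each sample. Set against the arrays, its columns correlated at 0.880 to 0.995 with the log2 calibrated ratios of treated over control and at 0.866 to 0.994 with the values used here, and their medians ran from 0.0053 to 0.0496. Their scale and direction were thus found from the arrays, and their normalization stays unknown. Slide and scan date are not given in the sources used here, so no batch was tested.

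The plan named normexp background correction unless the column was already corrected. It was, so intensities were used as deposited plus an offset of 50 and normalized within each array by loess with a span of 0.3 in limma 3.58.1 under R 4.3.3 with the data.table package (version 1.17.8). Empty spots (960 of 36288) and spots with a quality score of 0 (420 to 855 per array) were left out. Log2 ratios were turned to treated over control, and the dye-swapped arrays of a sample were averaged, which cancels a dye effect. The dimmest 40% of probes by mean log2 intensity were left out, and each gene was represented by its brightest probe. Of 35328 probes, the platform annotation gave a single gene symbol for 21865 and several for 1014, and 12449 were not in it. Names were updated through the human gene number (21493 probes) or the transcript accession of the array files (2391), 11441 probes had no single gene name, and where both names existed they were the same for 98.9%. After the filter 10896 genes remained, 2613 of them with more than 1 probe. Genomic positions were not used here. Signal over background is given by the share of probes above the 95th percentile of empty spots, and precision by the number of arrays.

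No group had more than 1 sample, so tests treated related samples as replicates. With limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), the mean of the 5 PIA samples was tested against 0, that is against the shared PIA7, whose own spread is left out. LY294002 was tested against the 5 PIAs and each PIA against the other 4, with the lone sample assumed to vary like the others. The mean of PIA6 over 2, 6 and 12 h was tested against 0, where each time had its own DMSO control, as was the slope per hour over 0, 2, 6 and 12 h and the mean of the PIA6 samples at 6 h in 2 experiments, which the labels do not show to be separate RNA. Errors are SE from limma and intervals cover 95%. The interval of a share of genes is exact (Clopper-Pearson) and treats genes as independent. No paired analysis was possible because the samples have no replicate numbers that link groups, and no comparison had 3 samples in each of 2 groups, so no other splits of the samples were counted. A gene was called 2-fold changed in a single sample with a mean log2 ratio of at least 1 in size and at least 1.5-fold with the same sign on both arrays.

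Before the data were examined, the comparisons, the gene lists, the naming rule and most alternatives were fixed. The lists were tested with camera at an inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the 23 lists, and their members were counted over all genes tested and adjusted over the list alone. With an estimated correlation, camera also takes only the residual degrees of freedom of the fit. These were 4 for the class and for LY294002, 2 for the time course mean and 1 for PIA6 in both experiments. A list can therefore fail that test for want of samples, whether or not its genes are correlated. The lists were cholesterol synthesis and uptake, fatty acid synthesis, FOXO targets, PI3K-Akt pathway components, ATF4 and amino acid response, endoplasmic reticulum chaperones, immediate early transcription factors, ERK feedback genes, NF-kB targets and cytokines, p53 targets, glycolysis and hypoxia response, heat shock proteins, NRF2 targets, metallothioneins, lysosome and autophagy, G1/S and DNA replication, G2/M and mitosis, ribosome biogenesis and MYC targets, BCL2 family and cell death, actin cytoskeleton and SRF/YAP targets, interferon response, and markers of fibroblasts and leukocytes as other cell types. Cytosolic ribosomal proteins and respiratory chain subunits were added after the data were seen, and only their medians are given. Named genes were, per fit, up to 12 higher and 12 lower with the largest mean log2 ratio among those that passed with the same sign in every treated sample (5 each way for single PIAs, 6 for the slope). For a difference, the sign was that of the difference from each other PIA. Where none passed, the 5 each way with the smallest p were taken, and the text gives some of them for single PIAs. Up to 5 each way were taken for single samples and up to 4 members for a list. Y-linked genes and XIST, 35 genes with a probe name in all, were left out.

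The pipeline was tested on simulated data with 50 genes changed at each of several sizes. The noise in every fit was the spread of each gene between the 5 PIA samples compared with PIA7. At 2-fold, the fits recovered 96% of them for the PIA class, 42% for LY294002 against the class, 30% for a single PIA against the others, 84% for the time course mean, 0% for the slope and 16% for PIA6 in both experiments. At 4-fold the shares were 100%, 82%, 84%, 90%, 50% and 88%. The time course samples may vary more than the PIA samples. In the real data the median SE was 0.178 for the time course mean and 0.182 for LY294002 against the class. Their 2-fold shares in the simulation were 84% and 42%, so the shares for the time course mean and the slope may be too high. The 16% for PIA6 in both experiments does not carry over to the real data. There that fit gave every gene 1 pooled SE of 0.17, so it acted as a single bound on the mean log2 ratio. A second simulation gave 5 unchanged samples a shared control, 20 times, with the noise of the 0 h sample taken as RNA noise and divided equally between treated and control. This can overstate the sharing if part of that noise is technical.

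Alternatives were print-tip loess, median centring of each array, no background correction, scale normalization between arrays, no dim filter or the dimmest 60% left out, the mean over a gene's probes, the authors' matrix, arrays of a single dye orientation, eBayes with trend and robust options, each sample left out in turn, PIA6 against DMSO added to the class, the 0 h sample subtracted, 6 and 12 h only, log2 of hours plus 1, and 1.5-fold as the size. Chosen after seeing the data were normexp on foreground and background, no offset with a floor of 1, removal of the 0 h profile by regression, the sign of the 6 h sample turned, and the class without PIA6 and PIA25. A result kept its call when it stayed on its side of the threshold in the same direction, a result that did not pass either way was not counted as turned, and a count was the same within 1.5 times.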

Results

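Gene expression was measured in H157, a human non-small cell lung cancer cell line, on 2-colour oligonucleotide arrays that each carried a treated and a control RNA. The 10 samples formed 10 groups of 1 sample, and each sample was a pair of dye-swapped arrays of the same RNA, so it counted as 1 replicate. In a time course, 10 µM PIA6, a phosphatidylinositol ether lipid analogue (PIA), was compared with time-matched DMSO, the solvent, at 0, 2, 6 and 12 h. In a compound comparison, 10 µM PIA5, PIA6, PIA23, PIA24, PIA25 or LY294002, an inhibitor of phosphoinositide 3-kinase (PI3K), was compared at 6 h with PIA7, described in the labels as inert. The series title names the PIAs as inhibitors of Akt, a kinase that acts after PI3K. The median intensity of a channel ran from 149 to 1569 units, and 85.6% to 98.9% of the gene probes lay above the 95th percentile of empty spots. Across probes, the dye-swapped arrays, turned to treated over control, correlated at 0.715 for PIA6 at 12 h, 0.643 at 6 h and 0.528 at 2 h against DMSO. The value was -0.479 for the 0 h sample, 0.202 for LY294002, and -0.0904 for PIA6 against PIA7, and lay between 0.377 (PIA25) and 0.541 (PIA24) for the other PIAs. All values are log2 ratios of treated over control, and the number of arrays limits their precision.

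The PIA class was compared with PIA7 to find transcripts shared by the 5 compounds. CXCL8, which encodes the chemokine interleukin 8, was higher than with PIA7 by 3.64 ± 0.12 (SE, n = 5; adjusted p = 4.96e-06), and KLF2, a Krüppel-like transcription factor, by 3.28 ± 0.12 (adjusted p = 5.45e-06). RHOB, a small GTPase, was higher by 2.67 ± 0.09, and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, by 2.52 ± 0.10. The other genes with the largest higher ratios were the kinase gene MAP3K2 (3.12 ± 0.17), TM4SF1 (2.88 ± 0.21), the protease inhibitor gene TFPI2 (2.33 ± 0.21), PREX1 (2.29 ± 0.10), the pseudokinase gene TRIB1 (2.20 ± 0.16), the cytokine gene IL24 (1.95 ± 0.15), the cathepsin gene CTSL (1.94 ± 0.21) and STC1 (1.90 ± 0.22). Lower transcripts included MCM3, a subunit of the replicative helicase (-1.70 ± 0.11), HSPA1A, an inducible heat shock protein (-1.51 ± 0.13), the kinase gene NUAK2 (-1.45 ± 0.10), the insulin-like growth factor binding protein gene IGFBP3 (-1.36 ± 0.06), the histone gene H2BC3 (-1.52 ± 0.14) and TMPO, a lamina-associated protein (-1.32 ± 0.20). NEK4 (-2.43 ± 0.20), LRRC46 (-1.88 ± 0.27), ODAD3 (-1.60 ± 0.15), CFAP53 (-1.55 ± 0.13), CUX2 (-1.35 ± 0.09) and BTN3A1 (-1.34 ± 0.10) were also among the lowest. Each of these 24 genes had the same sign in all 5 PIA samples. A further probe of PREX1, NEK4, ODAD3, CUX2 and BTN3A1 did not share the change (PIA means of 0.06, -0.09, 0.20, 0.29 and -0.32), and probes of HSPA1A and H2BC3 may bind related family members.

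**Figure D1:**
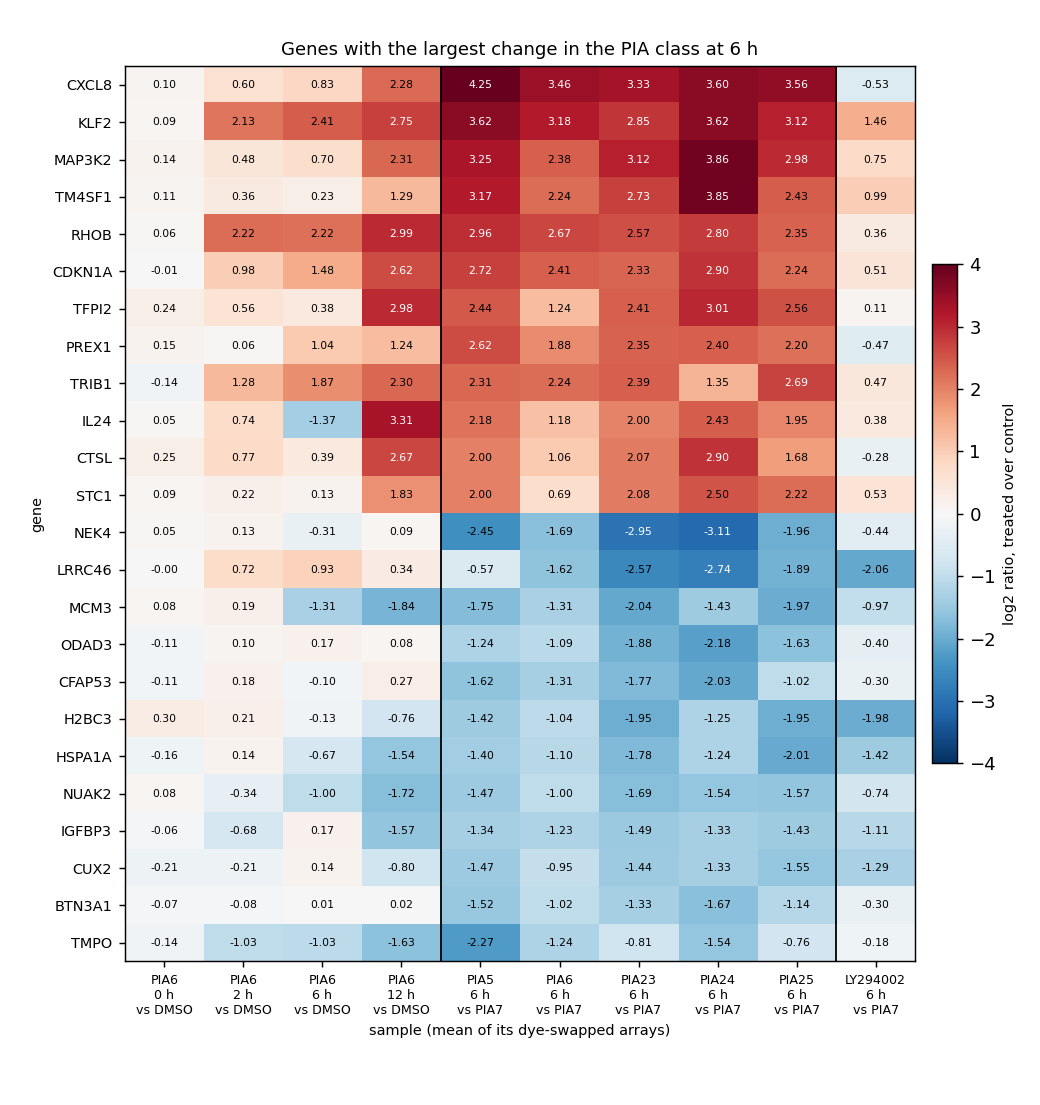
Log2 ratio (colour and printed value) of the 24 genes with the largest change in the PIA class, by gene (vertical) and sample (horizontal), each sample the mean of its dye-swapped arrays. KLF2 and RHOB lay above 2 in all PIA samples and at 2, 6 and 12 h of PIA6 against DMSO, whereas NEK4 lay between -3.11 and -1.69 in the PIA samples and between -0.31 and 0.13 against DMSO.

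In all, 2350 of 10739 genes passed, 1171 higher and 1179 lower, and of these 64 were at least 2-fold higher and 35 at least 2-fold lower. PIA7 was a single control shared by the 5 samples. A simulation of 20 sets of unchanged samples with 1 shared control gave a median of 3151.5 calls (3068 to 3254). That is more calls than were observed. None of the simulated calls was of 2-fold size. This was nearly fixed in advance, since no gene reached 2-fold in the 0 h sample that gave the noise. It therefore cannot show that the 2-fold genes exceed an effect of the shared control. The noise came from the 0 h sample, whose dye-swapped arrays correlated at -0.479, and at -0.333 less the dye effect common to the samples. Much of it may thus be technical and the simulated count too high. The total count alone cannot show whether there was change beyond the shared control. The count was 1473, 1369 or 1551 without PIA5, PIA23 or PIA25, and the split moved to 845 higher and 1300 lower with median centring and to 1311 and 1020 with the authors' matrix, while the 2-fold counts stayed between 60 and 73 higher and between 30 and 46 lower when 1 sample was left out.

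Several gene lists moved up against PIA7 in the PIA class by the camera test, which compares a list with all other genes. The member counts and the camera p values, here and below for the PIA class against PIA7, come from the fit that leaves out the spread of PIA7. A list shifted in the single PIA7 sample alone would move the same way in every PIA. The p values therefore cannot tell such a shift from an effect of the PIAs. The counts are to be read against all 10739 genes, of which 1171 were higher and 1179 lower. Of the immediate early transcription factors, 11 of 19 measured members were higher and none lower (adjusted p = 6.83e-07; adjusted p = 0.238 with an estimated correlation). There were 13 higher and 1 lower adjusted over the list alone. They included KLF2, ZFP36, which encodes an mRNA-destabilising protein (1.54 ± 0.08), and JUND (1.26 ± 0.12), while IER3 (1.60 ± 0.14) had another probe at 0.43. Of the NF-kB targets and cytokines, 9 of 16 were higher (adjusted p = 3.47e-05; adjusted p = 0.238 with an estimated correlation), and 10 adjusted over the list alone. CXCL8 was followed by LIF (1.83 ± 0.09), CXCL2 (1.81 ± 0.14) and RELB (0.74 ± 0.13). Of the lysosome and autophagy genes, 6 of 20 were higher (adjusted p = 0.00035; adjusted p = 0.30 with an estimated correlation), and 9 adjusted over the list alone. CTSL led, before the cholesterol transporter gene NPC1 (1.44 ± 0.08), CTSB (0.92 ± 0.07) and the autophagosome gene MAP1LC3B (0.91 ± 0.08). The median of this list ran from 0.0046 in PIA25 to 0.46 in PIA24, but was -0.22 in PIA6 against DMSO at 6 h. In the fit of PIA6 in both experiments, 3 of its 21 members were higher and 2 lower (adjusted p = 0.99). Of the ATF4 and amino acid response genes, 6 of 21 were higher (adjusted p = 0.00219; adjusted p = 0.285 with an estimated correlation), and 10 higher and 1 lower adjusted over the list alone. TRIB3 was at 1.18 ± 0.12, CTH at 0.94 ± 0.07, DDIT4 at 0.90 ± 0.08 and SESN2 at 0.48 ± 0.09. The median of cytosolic ribosomal proteins, a list added after the data were seen, ran from -0.26 in PIA23 to 0.32 in PIA24, and that of the ATF4 list from 0.14 in PIA25 to 0.37 in PIA24. In PIA6 against DMSO at 6 h the ATF4 median was -0.14, and the list did not pass for PIA6 over both experiments (adjusted p = 0.336).

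Lists that moved down in the PIA class were led by the G1/S and DNA replication genes. Of these, 14 of 20 were lower, both over all genes tested and adjusted over the list alone (adjusted p = 5.33e-08; adjusted p = 0.238 with an estimated correlation). MCM3 was followed by PCNA, the DNA polymerase clamp (-1.03 ± 0.11), the helicase subunit MCM4 (-0.99 ± 0.11) and the licensing factor CDT1 (-0.95 ± 0.09). Of the heat shock proteins, 9 of 14 were lower (adjusted p = 0.000215; adjusted p = 0.285 with an estimated correlation), and 9 lower and 1 higher adjusted over the list alone. HSPA1A was followed by HSPA8 (-1.06 ± 0.19), DNAJA1 (-0.96 ± 0.15) and HSPH1 (-0.81 ± 0.14). Of the G2/M and mitosis genes, 4 of 19 were lower (adjusted p = 0.00654; adjusted p = 0.285 with an estimated correlation), and 7 adjusted over the list alone. The 4 were CCNA2, which encodes cyclin A2 (-0.96 ± 0.12), CDC20 (-0.84 ± 0.15), the spindle kinesin gene KIF11 (-0.74 ± 0.09) and BIRC5 (-0.66 ± 0.07). Of the ribosome biogenesis and MYC targets, 8 of 18 were lower and 1, ODC1 (0.54 ± 0.13), was higher (adjusted p = 0.0043; adjusted p = 0.285 with an estimated correlation). Adjusted over the list alone, 9 were lower and 1 higher, with NOP56 at -0.69 ± 0.08 and DKC1 at -0.49 ± 0.07. This list did not pass for PIA6 over both experiments (adjusted p = 0.0965).

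The other 15 lists did not pass (adjusted p from 0.106 to 0.993). Of 22 cholesterol synthesis and uptake genes, 1 was higher and 3 were lower (HSD17B7, DHCR7 and LSS). Of 14 fatty acid synthesis genes, 1 was higher (ELOVL6, 0.34 ± 0.07) and 2 lower (SREBF1, -0.62 ± 0.09, and PNPLA3, -0.54 ± 0.07). Of 13 FOXO targets, a list close to Akt, 3 were higher (PINK1, 0.55 ± 0.07, BNIP3L, 0.50 ± 0.07, and SOD2, 0.35 ± 0.07). So were 2 of 16 PI3K-Akt pathway components (AKT2, 0.47 ± 0.10, and GSK3A, 0.26 ± 0.06). Of 13 ERK feedback genes, 5 were higher and 2 lower, with PHLDA1 at 1.21 ± 0.07 and the phosphatase gene DUSP5 at 1.11 ± 0.12. Of 13 p53 targets, 4 were higher and 2 lower, with CDKN1A followed by TNFRSF10B (0.90 ± 0.14). Of 16 BCL2 family and cell death genes, 2 were higher and 2 lower, with the survival gene MCL1 at 1.12 ± 0.09. The counts higher and lower were 5 and 2 of 14 endoplasmic reticulum chaperones, 2 and 1 of 20 glycolysis and hypoxia response genes, and 1 and 2 of 15 NRF2 targets. They were 3 and 4 of 18 actin cytoskeleton and SRF/YAP targets, and 1 and 3 of 12 interferon response genes. Of 7 metallothioneins, 1 was higher (MT1E, 0.56 ± 0.11, with another probe at -0.16). Of the markers of other cell types, 1 of 9 leukocyte markers was higher (CD68, 0.64 ± 0.09), and in limma none of 9 fibroblast markers passed. Of these, 1 had an unadjusted p under 0.05, and the largest ratio was that of COL1A2 at 0.23 ± 0.14 (adjusted p = 0.282). Adjusted over the list alone, the counts differed for fatty acid synthesis (2 higher and 4 lower), ERK feedback (6 and 3), glycolysis (2 and 0), BCL2 family (3 and 2), actin (4 and 5) and interferon genes (2 and 3).

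**Figure D2:**
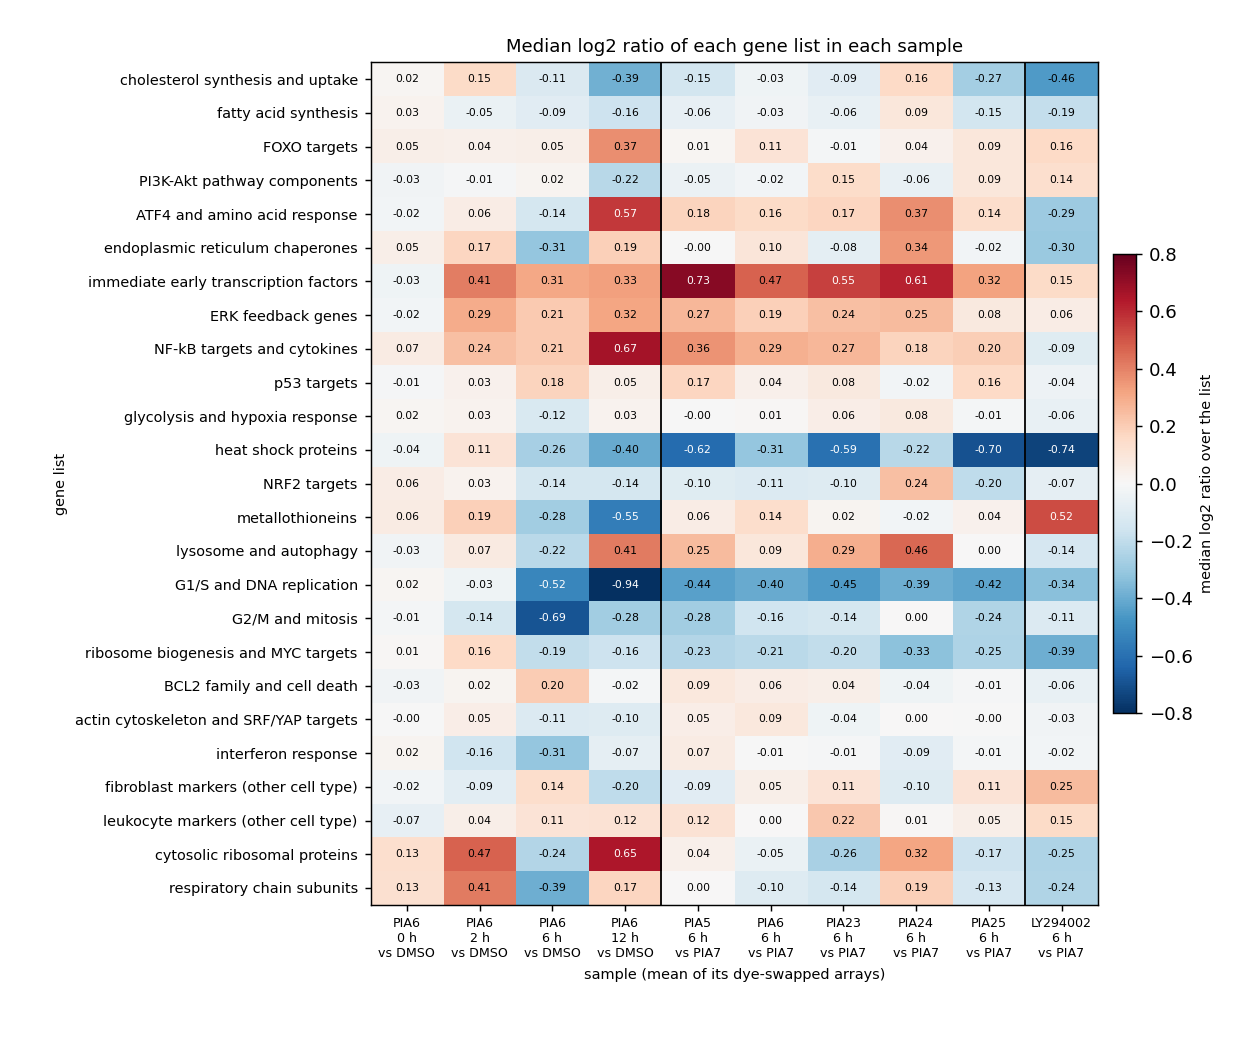
Median log2 ratio (colour and printed value) of each gene list (vertical) in each sample (horizontal), with 2 lists, cytosolic ribosomal proteins and respiratory chain subunits, added after the data were seen. The median of G1/S and DNA replication genes lay between -0.45 and -0.34 in the samples compared with PIA7 and at -0.52 and -0.94 after 6 and 12 h of PIA6 against DMSO, and that of ribosomal proteins ran from -0.26 in PIA23 to 0.65 at 12 h.

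PIA6 at 6 h was the only treatment measured against both controls. Its ratio to DMSO does not rest on PIA7, whereas a fit or list test over both samples does so in part. The labels do not say whether the PIA6 RNA was the same in both, so these samples may not be independent replicates. KLF2 was higher in both samples (2.41 against DMSO and 3.18 against PIA7), as were RHOB (2.22 and 2.67), TRIB1 (1.87 and 2.24), CDKN1A (1.48 and 2.41), the integrin gene ITGA6 (1.70 and 1.12) and HMOX1, which encodes heme oxygenase 1 (1.42 and 1.35). H2AX, a histone variant that marks DNA breaks, was lower in both (-2.0 and -1.35), as were MCM3 (-1.31 in each), the cyclin gene CCNA2 (-1.42 and -0.65), the primase gene PRIM1 (-1.07 and -1.03), PCNA (-1.09 and -0.93) and E2F2, a cell cycle transcription factor (-1.33 and -0.73). CXCL8 reached 0.83 against DMSO and 3.46 against PIA7, MAP3K2 0.70 and 2.38, and IL24 -1.37 and 1.18, so their sizes or signs differed between the experiments. In the limma fit over both samples, 746 of 10812 genes passed, 402 higher and 344 lower, 40 and 14 of them by 2-fold. In camera, 8 lists passed. Higher were immediate early transcription factors (8 of 19, 9 adjusted over the list alone), ERK feedback genes (5 of 13, 6 adjusted over the list alone), NF-kB targets (5 of 16, 5 adjusted over the list alone), p53 targets (3 of 13, 3 adjusted over the list alone) and BCL2 family genes (2 of 15, 2 adjusted over the list alone). Lower were G1/S genes (8 of 20, 13 adjusted over the list alone), G2/M genes (8 of 19, 11 adjusted over the list alone) and heat shock proteins (3 of 13, 5 lower and 1 higher adjusted over the list alone). The other 15 lists had adjusted p from 0.0965 to 0.99. The adjusted p of the 8 ran from 7.84e-17 to 0.0398, and each had an adjusted p = 0.665 with an estimated correlation. With an estimated correlation the test had 1 residual degree of freedom, so hardly any list could pass it. The 2-sample fit gave every gene 1 pooled SE of 0.17, and the count fell to 62 with the authors' matrix (45 higher, 17 lower) and to 128 with median centring (94 and 34), while with no filter on dim probes 325 were higher and 422 lower.

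Genes called in the PIA class were then read in PIA6 against DMSO, where PIA7 is not the control. Of the called genes, 68.7% had the same sign at 6 h (95% exact interval, 66.8% to 70.6%) and 81.7% at 12 h (80.1% to 83.3%), against 55.9% and 62.4% of all genes tested and 45.1% in the 0 h sample. Of the 64 genes that were 2-fold higher in the class, 17 were 2-fold higher at 6 h and 50 at 12 h against DMSO. Of the 35 that were 2-fold lower, 7 and 10 were 2-fold lower at those times. NEK4, ODAD3, CFAP53 and BTN3A1 lay between -0.31 and 0.27 and LRRC46 between 0.34 and 0.93 at 2, 6 and 12 h against DMSO.

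Each PIA was set against the other 4 at the same dose and time, where the shared PIA7 control cancels. PIA24 had lower transcripts of SLC19A2, a thiamine transporter gene, by -1.90 ± 0.14 (adjusted p = 0.0217), C1GALT1, an O-glycan galactosyltransferase gene (-1.71 ± 0.15), DCLRE1C, a DNA repair nuclease gene (-1.67 ± 0.13), RAB3C (-1.63 ± 0.17), ZNF687 (-1.46 ± 0.15) and MAML1 (-1.45 ± 0.14), the last named after its value was seen; with the mean over probes DCLRE1C (-0.74) and ZNF687 (-0.98) did not pass. In these 6 genes PIA24 lay below each of the other 4 PIAs, and 6 was the number past the threshold, with 1909 genes at an unadjusted p under 0.05. No gene passed in limma for PIA5, PIA6, PIA23 or PIA25, with 314, 428, 119 and 280 genes at an unadjusted p under 0.05. The genes with the smallest p, none of which passed, were ANKZF1 (2.02 ± 0.21, adjusted p = 0.180) for PIA5, CDKN2A (-1.57 ± 0.15, adjusted p = 0.196) for PIA6, LPCAT1 (0.65 ± 0.16, adjusted p = 0.997) for PIA23 and BCL2L2 (-1.63 ± 0.19, adjusted p = 0.171) for PIA25. The 95% interval of a difference reached a median of 0.37 (PIA24) to 0.45 (PIA23 and PIA25) to either side, so smaller differences between the compounds stay open. Larger ones can be missed too, since the simulation for a single PIA recovered 30% of 2-fold and 60% of 3-fold changes. The calls were lost without PIA5, PIA6 or PIA23, where the ratios of the first 5 genes stayed between -1.94 and -1.41 with fewer samples to test them. DCLRE1C was at 0.22 with no offset on the intensities. The brightest probe of a gene was picked anew in each setting, and DCLRE1C has 2 probes. With the offset kept, the mean over its probes was -0.74 against -1.67 for the brightest, so its other probe was not lower in PIA24. The turn can therefore come from the other probe alone, but which probe was picked with no offset was not checked. Over the 5 compounds, Cy5 arrays alone gave 186 lower and 2 higher, but Cy3 arrays alone gave 93 and the authors' matrix 19, all of them higher, and SLC19A2, C1GALT1, DCLRE1C, RAB3C and ZNF687 passed for PIA24 with Cy5 arrays alone (-3.23 to -2.45) and not with Cy3 arrays alone (-0.58 to -0.20) or the matrix (-1.57 to -0.96).

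LY294002 was compared with the PIA class to see where a PI3K inhibitor differed. CXCL8 was lower with LY294002 than with the PIAs by -4.17 ± 0.30 (adjusted p = 0.00492), with LY294002 itself at -0.53 against PIA7. The same held for the transcription factor gene BHLHE40 (-2.49 ± 0.25), the proteoglycan gene SDC1 (-2.33 ± 0.23), RHOB (-2.31 ± 0.22), the cytokine gene LIF (-2.31 ± 0.23), TRIB3 (-2.28 ± 0.29) and CDKN1A (-2.01 ± 0.25), and for PREX1 (-2.76 ± 0.25), DRC3 (-1.77 ± 0.23), the GTPase gene RND3 (-1.76 ± 0.22), FLOT2 (-1.63 ± 0.22) and COMTD1 (-1.46 ± 0.17). IRAK2 (-1.22 ± 0.17), named after its value was seen, was also among the 14 of 10730 genes that passed. In all 14, LY294002 lay below each of the 5 PIAs. An unadjusted p under 0.05 was found for 1158 genes, 763 of them lower. KLF2, at 1.46 in LY294002, was 1 of 5 genes 2-fold higher in both, with CXXC5, KLHL31, MAFK and TEX101. MCM3 (-0.97), PCNA (-1.07) and HSPA1A (-1.42) had ratios below 0 in the LY294002 sample, which were not tested by themselves. The count was 6, 9 or 7 without PIA5, PIA6 or PIA23 and 73 without PIA24, and the lone LY294002 sample was assumed to vary like the PIA samples.

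**Figure D3:**
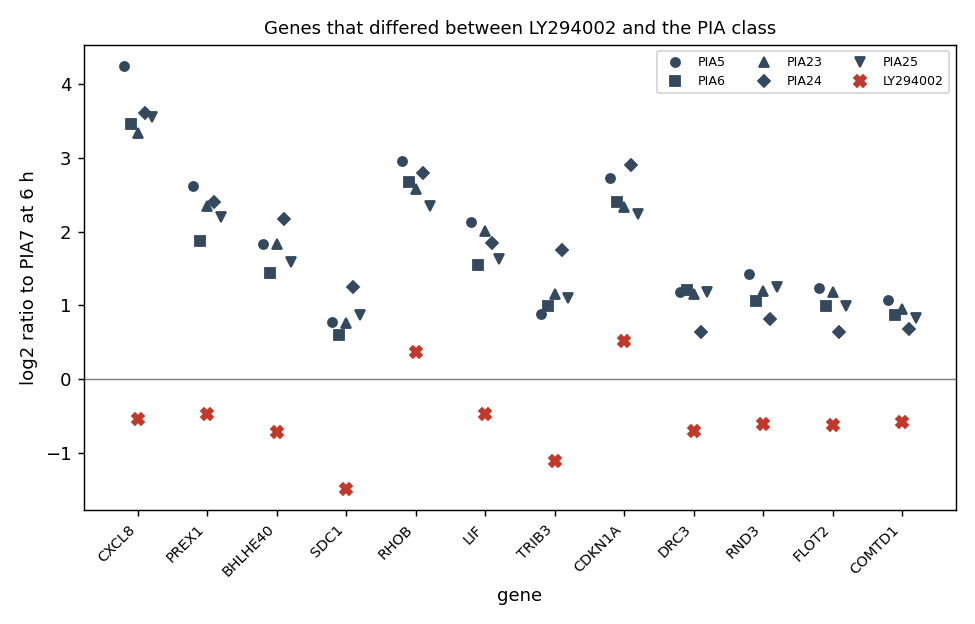
Log2 ratio to PIA7 at 6 h (vertical) of the 12 genes (horizontal) that differed most between LY294002 and the PIA class, with 1 point per compound. CXCL8 lay between 3.33 and 4.25 in the PIAs and at -0.53 in LY294002.

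By list, 9 of 23 differed between LY294002 and the PIA class in camera, and none did with an estimated correlation (lowest adjusted p = 0.178). The other 14 had adjusted p from 0.0511 to 0.943. The ATF4 and amino acid response genes were lower with LY294002 (median -0.62, adjusted p = 5.41e-11; adjusted p = 0.178 with an estimated correlation). TRIB3 passed over all genes, and 9 of 21 members adjusted over the list alone. PSAT1, a serine synthesis gene, was at -1.39 ± 0.28, DDIT4 at -1.35 ± 0.21 and the amino acid transporter gene SLC7A5 at -1.34 ± 0.22, which did not pass over all genes. Lysosome and autophagy genes were lower (median -0.45, adjusted p = 0.00023; adjusted p = 0.25 with an estimated correlation), with 5 of 20 lower adjusted over the list alone. NF-kB targets were lower (median -0.23, adjusted p = 0.00034; adjusted p = 0.239 with an estimated correlation), CXCL8 and LIF over all genes and 5 of 16 adjusted over the list alone. Immediate early transcription factors were lower (median -0.33, adjusted p = 0.000547; adjusted p = 0.239 with an estimated correlation), with 7 lower and 1 higher adjusted over the list alone. Cholesterol synthesis and uptake genes were lower (median -0.32, adjusted p = 0.00034; adjusted p = 0.29 with an estimated correlation). HMGCS1, at -1.55 ± 0.42, did not pass. Metallothioneins (median 0.39, adjusted p = 0.00828; adjusted p = 0.239 with an estimated correlation; 1 of 7 adjusted over the list alone) and G2/M genes (median 0.26, adjusted p = 0.00545; adjusted p = 0.239 with an estimated correlation; 0 of 19) were higher. Endoplasmic reticulum chaperones (median -0.22, adjusted p = 0.0118; adjusted p = 0.361 with an estimated correlation; 3 of 14 adjusted over the list alone) and glycolysis genes (median -0.12, adjusted p = 0.0419; adjusted p = 0.239 with an estimated correlation; 1 of 20) were lower. In limma, no member of the lysosome, cholesterol, immediate early, metallothionein, G2/M, chaperone or glycolysis lists passed over all genes. In the direction of the list, 8, 6, 7, 2, 4, 4 and 5 of them had an unadjusted p under 0.05. The cytosolic ribosomal proteins had medians of -0.25 in LY294002, -0.26 in PIA23, -0.17 in PIA25 and 0.32 in PIA24, and the fibroblast markers 0.25 in LY294002, 0.11 in PIA23 and in PIA25, 0.05 in PIA6, -0.09 in PIA5 and -0.10 in PIA24.

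The time course asked which transcripts PIA6 changed over 2, 6 and 12 h against DMSO. RHOB was higher by 2.48 ± 0.20 (SE, n = 3; adjusted p = 0.00332), KLF2 by 2.43 ± 0.18 (adjusted p = 0.00332), TRIB1 by 1.82 ± 0.21 (adjusted p = 0.0354) and KLF6, another Krüppel-like factor, by 1.73 ± 0.17 (adjusted p = 0.0138), each in all 3 samples. RHOB, KLF2 and KLF6 were already at 2.22, 2.13 and 1.54 at 2 h, and all 4 lay between -0.14 and 0.09 at 0 h. CDKN1A went from -0.01 at 0 h to 0.98, 1.48 and 2.62, but its mean of 1.69 ± 0.28 did not pass (adjusted p = 0.25). These 4 were the genes called among 10833, with 507 at an unadjusted p under 0.05. The count was 91 without the 2 h sample, and 0 without the 6 h sample, with no filter on dim probes or with the authors' matrix, although the ratios of RHOB, KLF2, TRIB1 and KLF6 stayed between 1.73 and 2.65 there.

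**Figure D4:**
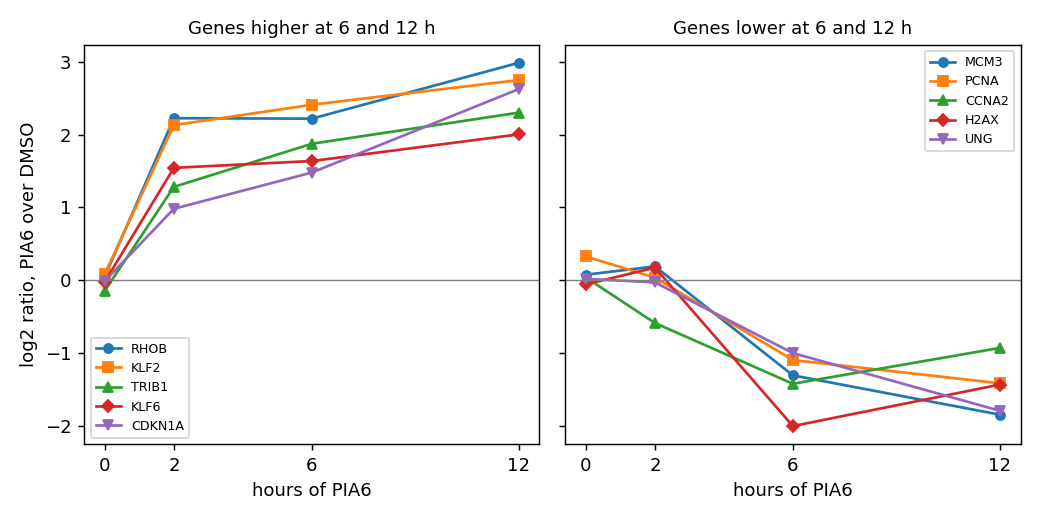
Log2 ratio of PIA6 over DMSO (vertical) by hours of treatment (horizontal) for 10 genes, with 1 sample per time. RHOB and KLF2 lay above 2 from 2 h on, and MCM3 reached -1.31 at 6 h and -1.84 at 12 h.

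Over the same times, 8 of 23 lists passed in camera and none with an estimated correlation (lowest adjusted p = 0.548). Immediate early transcription factors were higher (median 0.38, adjusted p = 3.7e-08; adjusted p = 0.548 with an estimated correlation; KLF2 and KLF6 over all genes and 9 of 19 adjusted over the list alone). NF-kB targets (median 0.31, adjusted p = 4.55e-05; adjusted p = 0.614 with an estimated correlation; 6 of 16 adjusted over the list alone) and ERK feedback genes (median 0.19, adjusted p = 0.00024; adjusted p = 0.574 with an estimated correlation; 4 of 13 adjusted over the list alone) were higher. So were ATF4 response genes (median 0.19, adjusted p = 0.00271; adjusted p = 0.647 with an estimated correlation; 0 of 21 adjusted over the list alone) and p53 targets (median 0.07, adjusted p = 0.0158; adjusted p = 0.574 with an estimated correlation; 1 of 13). G1/S genes were lower (median -0.53, adjusted p = 2.02e-12; adjusted p = 0.598 with an estimated correlation; 1 of 20 adjusted over the list alone), as were G2/M genes (median -0.34, adjusted p = 6.42e-09; adjusted p = 0.574 with an estimated correlation; 7 of 18 adjusted over the list alone) and heat shock proteins (median -0.21, adjusted p = 0.0176; adjusted p = 0.647 with an estimated correlation; 0 of 13). In limma no member of the NF-kB, ERK feedback, ATF4, p53, G1/S, G2/M or heat shock lists passed over all genes, where 6, 4, 2, 3, 9, 7 and 1 members had an unadjusted p under 0.05 in the list's direction. The other 15 lists had adjusted p from 0.0691 to 0.953. The ATF4 list's median was 0.06 at 2 h, -0.14 at 6 h and 0.57 at 12 h, while the ribosomal protein median was 0.47, -0.24 and 0.65. The ribosomal protein median was already 0.13 at 0 h, so these values are not all due to time on PIA6. Respiratory chain subunits had medians of 0.13, 0.41, -0.39 and 0.17 at 0, 2, 6 and 12 h. The median of heat shock proteins was above 0 at 2 h (0.11) and below it at 6 h (-0.26) and 12 h (-0.40).

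No gene had a slope over 0, 2, 6 and 12 h that passed in limma (lowest adjusted p = 0.547), and 547 had an unadjusted p under 0.05. Those with the smallest p, none of which passed, were the collagenase gene MMP1 (0.24 ± 0.03 per hour), CD55 (0.21 ± 0.03), SLC38A2 (0.17 ± 0.02), SPRY2 (0.17 ± 0.02) and CDKN1A (0.20 ± 0.03) among higher slopes and PLK2 (-0.18 ± 0.03), UNG (-0.16 ± 0.03), NUAK2 (-0.15 ± 0.02), VIPR1 (-0.13 ± 0.02) and SLC2A4RG (-0.14 ± 0.03) among lower ones. The count was 4 without the 0 h sample, 13 without 2 h, 1107 without 6 h and 321 without 12 h.

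Single samples were summarised by genes at least 2-fold changed on average and 1.5-fold on both arrays, with no test. PIA6 against DMSO had 0 such genes at 0 h, 10 higher and 9 lower at 2 h, 86 and 71 at 6 h, and 309 and 68 at 12 h. At 12 h the largest were IL24 (3.31), RHOB (2.99), TFPI2 (2.98), KLF2 (2.75) and CD55 (2.73), and PLK2 (-2.08), MCM3 (-1.84) and UNG (-1.79). In the compound comparison the counts higher and lower were 116 and 58 for PIA5, 61 and 17 for PIA6, 88 and 85 for PIA23, 141 and 87 for PIA24, 72 and 65 for PIA25, and 21 and 44 for LY294002. All 5 PIAs shared 28 genes higher and 10 lower, and 11 of the 28 were also 2-fold higher in PIA6 against DMSO at 6 h. In LY294002 the largest ratios were those of TEX101 (3.39), CHCHD5 (2.97) and KLHL31 (2.90), and of LRRC46 (-2.06), H2BC3 (-1.98), HSPB8 (-1.85) and PSAT1 (-1.61).

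Log2 ratios were correlated across 10669 genes between all pairs of samples, and genes are not independent replicates. Among the PIAs, r ran from 0.45 (PIA6 with PIA24) to 0.89 (PIA23 with PIA25), where simulated unchanged samples with a shared control gave 0.50 and a covariance of 0.0068, against observed covariances of 0.0465 to 0.109. PIA23 and PIA25 were within 1.5-fold for 99.1% of the genes and 2-fold apart in 18. LY294002, which shares PIA7 too, correlated at 0.55 with PIA23, 0.54 with PIA25, 0.23 with PIA6, 0.20 with PIA5 and 0.03 with PIA24. The covariances were 0.0594 for PIA23, 0.0574 for PIA25, 0.0186 for PIA6, 0.0213 for PIA5 and 0.00345 for PIA24. Across the experiments, which share no control, PIA6 at 6 h against DMSO correlated at 0.46 with PIA6 against PIA7, and PIA6 at 12 h correlated at 0.59 with PIA24 and 0.53 with PIA5. Within the time course, the 6 h sample correlated at -0.44 with 0 h, -0.36 with 2 h and -0.01 with 12 h. The labels state the dye of each array, so its direction was kept.

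**Figure D5:**
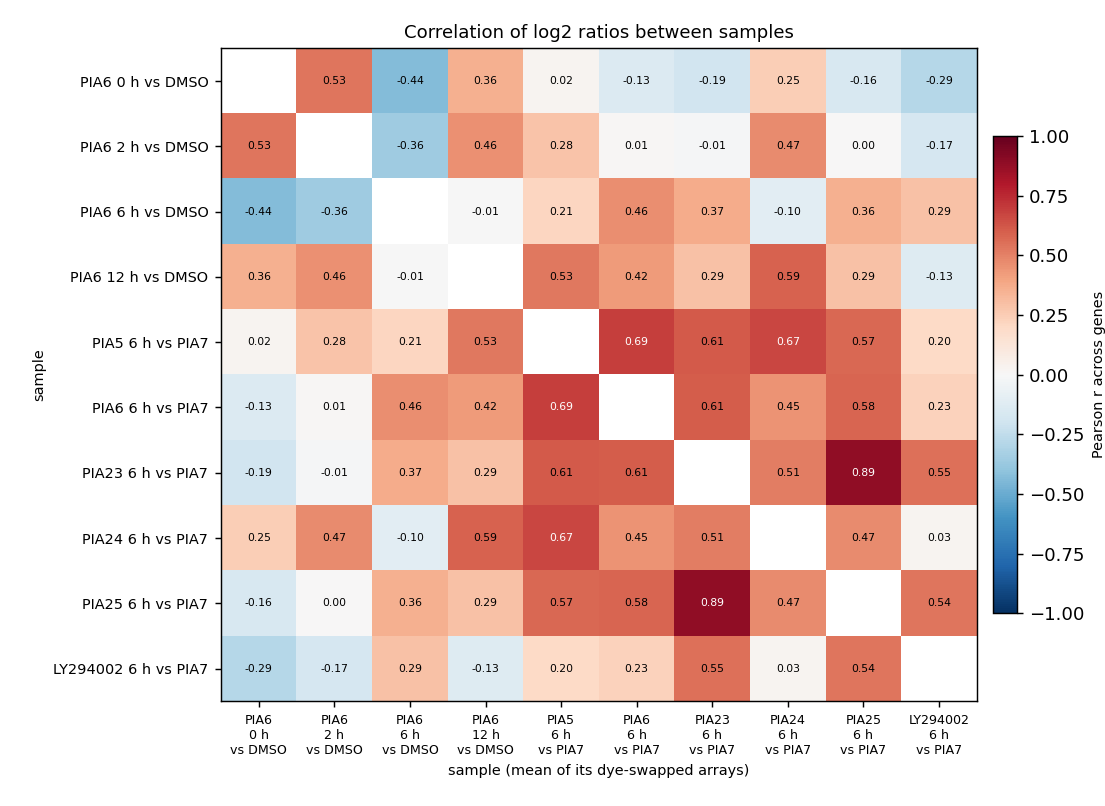
Pearson correlation across genes of the log2 ratios of each pair of samples (both axes), as colour and printed value. PIA23 and PIA25 correlated at 0.89, and the 6 h sample against DMSO correlated at -0.44 with the 0 h sample.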

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

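Chosen after the result was seen were both tests of the 6 h sample against DMSO and the tests of the 2-fold PIA class genes that LY294002 left unchanged. All 3 patterns were noticed in these data, so each reading below is a hypothesis.

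By a test of the difference itself, with 1 sample in an arm each time, LY294002 differed from the PIA class in 14 genes and PIA24 from the other 4 PIAs in 6 genes. The PIA24 genes rest on the Cy5 arrays: the 5 named ones lay between -3.23 and -2.45 there, and between -0.58 and -0.20 without passing in the Cy3 arrays. The PIA24 array with the treated RNA in Cy5 had a median treated intensity of 149, the lowest of any channel. Its control channel had 432. Whether this dim channel made the difference was not tested. In a group of 5, a sample stood apart when its gap to the nearest other sample exceeded 0.71 of the group's range. Of 56 values tested in the 5 PIAs, 4 had such a sample, where chance gives 2.8. STC1 was at 0.69 in PIA6, and the nearest PIA was at 2.00. DRC3 was at 0.63 in PIA24, with the nearest at 1.16. The median of the ATF4 and amino acid response genes was 0.37 in PIA24 against 0.18 in the nearest PIA, and that of the NRF2 targets was 0.24 in PIA24 against -0.10.

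Some genes called in the PIA class may owe their call to the shared PIA7 sample, since a ratio raised or lowered in PIA7 alone would enter all 5 PIAs and LY294002. Of the called genes, 48 were changed 2-fold or more the same way in LY294002, and in PIA6 against DMSO at 6 h their median ratio, turned to the class direction, was 0.062 (quartiles -0.18 and 0.38). At 6 h this is what the shared control needs for them as a set, but at 12 h the medians were 0.27 for the 17 higher and -0.26 for the 31 lower, both in the class direction, and KLF2 (2.41), PCNA (-1.09) and HSPA1A (-0.67) kept that direction at 6 h, so an effect of the PIAs stays open for part of them. The 2054 called genes under 1.5-fold in LY294002 had a median of 0.17 (quartiles -0.08 and 0.43), between the bounds set beforehand, so for them the shared control and an effect of the PIAs cannot be told apart with 1 PIA7 sample. The 56 of these with a class change of 2-fold or more had a median of 0.63; in tests by direction, chosen with their bounds after the medians were seen, the 46 higher genes had 0.70 (lower quartile 0.42), which argues against the shared control as their whole cause, while for the 10 lower genes (0.41, quartiles 0.02 and 0.77) it stays open.

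PIA23 and PIA25 correlated at 0.89 with each other and at 0.55 and 0.54 with LY294002, against 0.03 for PIA24 with LY294002. All share PIA7, and unchanged samples with a shared control gave 0.50 in a simulation. That value was set by the equal division of noise between treated and control. LY294002 also shares PIA7 with PIA5 and PIA6, where it correlated at only 0.20 and 0.23. The simulated 0.50 therefore cannot decide whether 0.55 and 0.54 show a resemblance to LY294002. The covariances (0.0594 and 0.0574) were above the simulated 0.0068, but so were those of LY294002 with PIA5 (0.0213) and PIA6 (0.0186). The simulated covariance rests on the noise of the 0 h sample and the same equal division, so it cannot decide this either. Position on the slide is an unlikely source, since PIA23 and PIA25 correlated at 0.893 after print-tip loess. A component already seen in the 0 h sample stays open. With that sample held fixed, the gap between the correlations of LY294002 with PIA23 and with PIA24 was 0.42, from 0.522. However, its dye-swapped arrays correlated at -0.479, so holding it fixed cannot take out such a component in full. The 0 h sample correlated at -0.19 with PIA23, -0.16 with PIA25 and -0.29 with LY294002, but at 0.25 with PIA24. A shared feature of these RNA samples other than treatment, such as the day of harvest, was not tested because no date is given, and the compounds stay open beside it; PIA7 enters all 6 samples alike, so it does not account for differences between pairs.

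PIA6 at 6 h against DMSO correlated at -0.44 with 0 h and -0.36 with 2 h. An exchange of treated and control on both arrays is argued against, because 68.7% of the genes called in the PIA class had the same sign in it. A component already present at 0 h stays open: with the 0 h sample held fixed, the correlation with 2 h was -0.16, neither near 0 nor near the plain value. The other sample of PIA6 at 6 h, against PIA7, correlated at 0.46 with this one but at -0.13 with 0 h and 0.01 with 2 h, and whether the control or a feature of this RNA pair made the difference was not tested.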

How the results depend on the processing

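Alternatives chosen after the data were seen were normexp, no offset with a floor of 1, removal of the 0 h profile, the turned sign of the 6 h sample, the class without PIA6 and PIA25, and all alternatives of the list tests and of the correlations. The causes of the changes below were not tested, except that fewer samples were fitted where samples were left out. The 24 genes named for the PIA class kept direction and call in 500 of 501 values, and 1 lost its call. The calls of the class's lists were kept in 294 of 299 values, with 7 to 9 lists passing against 8. Weaker were 54 of 228 values of the genes named for LY294002, 21 of 79 for the time course, 44 of 86 for PIA24 and 15 of 325 for PIA6 in both experiments. Of the genes named without passing, 17 of 196 values for the slope, 10 of 174 for PIA5, 7 of 175 for PIA6, 9 of 171 for PIA25 and 0 of 174 for PIA23 passed. DCLRE1C in PIA24 turned to 0.225 with no offset and a floor of 1, a setting in which the brightest probe of each gene was picked anew. Of the counts for single compounds or samples, 65 of 216 moved by more than 1.5 times. For 2-fold genes, the authors' matrix, single dye orientations and the mean over probes were counted without the rule of 1.5-fold on both arrays.

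The class count of 2350 became 1540 with the dimmest 60% left out, 3738 with Cy3 arrays only and 1199 without PIA6 and PIA25, and ran from 1369 to 2509 with 1 sample left out. The LY294002 count of 14 became 24 with print-tip loess, 35 with median centring, 8 with scale normalization, 6 with no dim filter, 32 with the dimmest 60% left out and 6 with the mean over probes. It was 9 with the authors' matrix, 24 with Cy3 arrays only, 9 with no offset and 47 with the 0 h profile removed, and ran from 6 to 73 with 1 sample left out. The count of 6 over single PIAs, all lower, became 16 with print-tip loess (12 lower), 2 with no background correction, 42 with no dim filter (39 lower), 0 with the dimmest 60% left out and 1 with the mean over probes. The direction turned with the authors' matrix (19, all higher) and with Cy3 arrays only (93, all higher), but not with Cy5 arrays only (188, of which 186 lower). It was 3 with trend and robust eBayes, and ran from 0 to 8 with 1 sample left out.

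The time course count of 4 became 2 with median centring, 2 with no background correction, 0 with no dim filter, 0 with the authors' matrix, 17 with Cy5 arrays only, 91 with 6 and 12 h only and 0 with the 6 h sign turned. It ran from 0 to 91 with 1 sample left out. The slope count of 0 ran from 4 to 1107 in fits with 1 time left out. The count of 746 for PIA6 in both experiments became 128 with median centring, 456 with the dimmest 60% left out, 233 with the mean over probes, 62 with the authors' matrix and 280 with Cy5 arrays only, and no sample could be left out of 2. The 1408 changes of 2-fold, over all samples but that of 0 h, became 871 with no background correction and 7189 at 1.5-fold. They became 2550 with the authors' matrix, 2410 with Cy5 and 2643 with Cy3 arrays only. These last counts were made without the rule of 1.5-fold on both arrays, so part of their rise comes from a looser rule. The median correlation among PIAs, 0.593, became 0.453 with no dim filter. Signal over background limits dim genes, and 1 sample per group limits every comparison.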

Other observations

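The values here are of lists and genes in single samples and were chosen for description after the data were seen, without a test of the difference between samples.

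After 12 h of PIA6 against DMSO, the median of the NF-kB targets and cytokines was 0.67, that of the ATF4 and amino acid response genes 0.57, that of the lysosome and autophagy genes 0.41 and that of the FOXO targets 0.37. In the same sample the median was -0.94 for the G1/S and DNA replication genes, -0.55 for metallothioneins, -0.40 for heat shock proteins and -0.39 for cholesterol synthesis and uptake genes. The ribosomal protein median stood at 0.65 there and at 0.13 in the 0 h sample. Earlier in the time course these lists did not all have the same sign. At 2 and 6 h the median was 0.07 and -0.22 for lysosome genes and 0.06 and -0.14 for ATF4 genes. It was 0.19 and -0.28 for metallothioneins, 0.11 and -0.26 for heat shock proteins and 0.15 and -0.11 for cholesterol genes. With LY294002 at 6 h, the median was 0.52 for metallothioneins, -0.74 for heat shock proteins, -0.46 for cholesterol genes and -0.39 for ribosome biogenesis genes, with ribosomal proteins at -0.25. Heat shock proteins had medians from -0.70 (PIA25) to -0.22 (PIA24) in the PIAs.

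TEX101, a germ cell surface protein gene, was at 2.18 after 2 h of PIA6 against DMSO, -1.42 at 6 h and 0.56 at 12 h. It was at -0.25 in PIA6 against PIA7, between 2.09 and 3.15 in the other PIAs and at 3.39 in LY294002. CXXC5 had 0.89, -0.78 and 0.06 at 2, 6 and 12 h, -0.67 in PIA6 against PIA7, and 1.15 to 1.87 in the other PIAs. Its 2 other probes had PIA means of 0.08 and 0.09.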
